A study of Mus musculus with 30 samples.

How the data were processed

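RNA-seq was made from cultures of the mouse pancreatic ductal adenocarcinoma lines T3-2D and NB508, with source KPC mouse and strain C57BL/6J, per the labels. Total RNA was taken with a phenol reagent, and libraries were prepared with a directional mRNA kit, per the labels' protocols. The 30 samples fall into 16 groups. Of these, 14 groups hold 2 libraries, labelled as biological replicates, and 2 libraries stand alone. In the knockdown groups of the stable series the replicates are different short hairpins against EVI1, so the spread within them is between hairpins. The labels name the same hairpins in T3-2D and NB508, and the Tet-shEVI1 libraries carry a hairpin from that set. The Tet-ON series received doxycycline at 1 uM.

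The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) in 6 tables, a column per library. They come from STAR alignments and Cufflinks estimates, per the submitters' processing notes, which give no versions or settings. The notes name the mouse builds mm10 and mm9 without saying which table used which. The tables name genes by symbol only. FPKM is normalised within a library and carries no count. The FPKM sum per library lay between 290259 and 367616 and is not a depth. Absolute depth is therefore unknown, and no counting interval is given. Relative depth was read from genes under 0.1 FPKM, where a value is close to a few fragments.

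The tables differ in what was listed. The NB508 table holds 10688 genes, has no value below 0.1 and no gene whose mean is below 1.1. The Tet-shEVI1 table holds 12098 genes and no zero. The other tables hold 20484 to 20486 genes with zeros. A value at the floor of a table (0, or 0.1 in NB508) beside 5 FPKM or more in another library of the same fit was found for widely used genes too. Such a gene is given as listed at that value, with each library's value and no fold. The single-library table repeats 399 symbols. The copy with the highest mean was kept, and 1 blank line was dropped from each of the stable T3-2D tables. All 30 columns of per-library values were used. Of the columns for the stable T3-2D knockdown, 1 carries the hairpin number 3064, while the label of the remaining sample gives 3604. That library enters its group without a replicate number and is called unnumbered here.

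Genes with at least 1 FPKM in at least 2 libraries of a fit were kept, and log2(FPKM + 1) was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), against both directions. Benjamini-Hochberg adjustment ran over the genes kept, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Each stable comparison used its own 4 libraries. Each time course was fitted over its 8 libraries, which share 1 estimate of the spread, with contrasts of 24, 48 and 72 h against 0 h and an F test over the 3 contrasts. The tables were normalised separately, so tests stay within a table. The test of the difference between the knockdowns in T3-2D and NB508 is the exception: it joins effects taken within each table, over 10150 genes. Overlaps of calls were tested with Fisher's exact test over genes tested in both fits, leaving out Mecom. The single libraries were compared by difference alone. Errors are SDs over the 2 libraries of a group, or standard errors (SE) of limma where named. Limma's p-values for genes measure the spread between these libraries. Those of Fisher's exact test come from counts of genes, which are not independent replicates. The time course tables hold no culture with doxycycline alone.

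Gene lists were written from general knowledge, 30 in all: reported EVI1 targets, PRDM factors and corepressors, foregut endoderm factors, classical and basal-like subtype markers, epithelial and mesenchymal genes, EGF family, MAPK output, cell cycle, interferon, NF-kappaB and cytokines, TGF-beta response, YAP targets, Wnt and Notch targets, hypoxia and glycolysis, cholesterol synthesis, p53 targets, ATF4 and unfolded protein response, NRF2 antioxidant genes, hemidesmosome and integrins, proteases, ribosomal proteins, replication histones, and markers of fibroblasts, leukocytes, endothelium, acinar cells, endocrine or neural cells and mitochondrial mRNA. A list needed 5 kept members. The mitochondrial, leukocyte, endothelial, acinar and endocrine or neural lists had fewer in every fit and gave no test, and the fibroblast list reached 5 in NB508 only. Lists were tested with camera at its preset correlation of 0.01 and with an estimated correlation, with Benjamini-Hochberg adjustment within a contrast. The fits left 2 residual degrees of freedom in the stable comparisons and 4 in the time courses, so the estimated form can call few lists. Member counts are over all genes tested, and a count adjusted over the list alone follows where it differs. Of 216 list tests, 81 passed with the preset correlation and 0 with the estimated correlation, while limma called between 0 and 7009 genes in the same fits and 157 to 7328 lay at an unadjusted p under 0.05. For the single libraries, a list's median difference is given as a percentile of 10000 random lists matched on expression.

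Samples, groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took Mecom and the 10 genes with the largest change in each direction among those past the test, with 5 FPKM or more in the higher group and the groups' libraries separated. For a time course it took the 10 each way with the largest mean change and 1 sign at all 3 times, for shared sets the 10 with the largest smaller change, and for a list up to 4 members with the smallest adjusted p. Where no gene passed, the same ranking is given as values. Unnamed gene models were passed over. Members of near-identical families, such as Serpina1a to Serpina1d, the Prl2c genes, Ly6a and Ly6c1, and Klra18, are uncertain, since shared reads could be split among them.

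The scripts were tested on simulated data (10 draws per comparison). Values were drawn at random around each gene's mean with limma's estimate of its spread. Changes of known size were added only to genes with a mean log2(FPKM + 1) above 4. Differences between whole libraries and correlation between genes were not simulated, so the shares below hold for better expressed genes under limma's own model. For the stable EVI1 comparison (10613 genes) 100% of 1.41-fold changes were recovered and 8.97% of calls were false. For the T3-2D knockdown (10586 genes) 72.6% of 1.41-fold and 100% of 2-fold changes were recovered, with 8.68% of calls false. For NB508 (10688 genes) 99.8% of 1.41-fold changes were recovered, with 7.32% of calls false. For Tet-shEVI1 at 72 h (10508 genes) 100% of 1.41-fold changes were recovered, with 6.67% of calls false. For Tet-EVI1 at 72 h (10612 genes) 0.8% of 1.41-fold, 15.2% of 2-fold and 87.6% of 4-fold changes were recovered, with 5.36% of calls false.

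Alternatives were a pseudocount of 0.1, no filter on low values, quantile normalisation, a median-of-ratios size factor per library, leaving out each library, and the replicate number as a block. Those added after seeing the data were leaving out genes at the floor, the block without the second Tet-EVI1 library at 72 h, calls of at least 2-fold in the overlaps, and an estimated correlation or leaving out that library for the sets of stable calls in the time courses. Where an arm is left with 1 library, limma pools the spread and the lone library is assumed to vary like the others. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.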

Results

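Gene expression was measured by RNA-seq in 30 libraries of mouse pancreatic ductal adenocarcinoma (PDA) cells in which EVI1, a zinc-finger transcription factor encoded by Mecom, was raised or lowered. The comparisons ask which genes follow gain and loss of EVI1. T3-2D cells carried an empty vector (n = 2) or stable EVI1 (n = 2), and either a control hairpin against Renilla luciferase (shRen, n = 2) or hairpins against EVI1 (shEVI1, n = 2). NB508 cells carried shRen (n = 2) or shEVI1 (n = 2). Inducible T3-2D cells were sampled at 0, 24, 48 and 72 h of doxycycline, with EVI1 (Tet-EVI1) or a hairpin against it (Tet-shEVI1), n = 2 at each time. A library labelled Tet-shRen and a Tet-shEVI1 library, both at 24 h, had no replicate.

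FPKM sums ran from 290259 to 367616 per library, and absolute depth is unknown. Relative depth within a table lay between 0.835 and 1.16 in the tables where it could be read, except Tet-EVI1. There the replicate 2 libraries held 2.89 (0 h), 1.70 (24 h), 2.85 (48 h) and 1.4 (72 h) times the depth of 0 h replicate 1. The NB508 table gave no relative depth. Replicates correlated across genes at r = 0.995 to 0.998, but at 0.988, 0.991, 0.988 and 0.953 in Tet-EVI1 at 0, 24, 48 and 72 h (genes are not independent replicates).

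Mecom, on the minus strand of chromosome 3 from 29951296 to 30548008 in GRCm38 (mm10), followed the labels in all groups. In T3-2D cells it read 7.51 and 7.48 FPKM with empty vector and 51.8 and 55.3 with EVI1, a log2 fold change of 2.68 (SE 0.06, adjusted p = 1.24e-08). With shRen it read 7.49 and 8.81, and with shEVI1 2.57 and 2.24, so that Mecom fell by 1.42 on the log2 scale (adjusted p = 0.00237). In NB508 cells Mecom was 12.7 and 12 with shRen and 2.07 and 2.27 with shEVI1, where it fell by 2.07 (adjusted p = 6.46e-07). In Tet-EVI1 cells Mecom averaged 10.2 ± 1.12 (SD, n = 2) at 0 h and 19.7 ± 6.88, 22.9 ± 4.8 and 24.8 ± 6.41 at 24, 48 and 72 h of doxycycline. The libraries read 9.37, 14.9, 19.5 and 20.2 in replicate 1 and 10.9, 24.6, 26.2 and 29.3 in replicate 2. None of the 3 times passed limma's test, with adjusted p of 1, 1 and 0.545. In Tet-shEVI1 cells Mecom fell from 5.72 ± 0.122 to 1.87 ± 0.0514, 1.70 ± 0.459 and 1.49 ± 0.0706, with adjusted p = 4.84e-05, 2.93e-05 and 1.44e-05. The single libraries read 7.10 in the library labelled Tet-shRen and 3 in Tet-shEVI1. Limma's p-values for genes measure the spread between these libraries throughout. Those of Fisher's exact test come from counts of genes, which are not independent replicates. Levels in different tables were normalised separately and were not tested against each other.

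**Figure D1:**
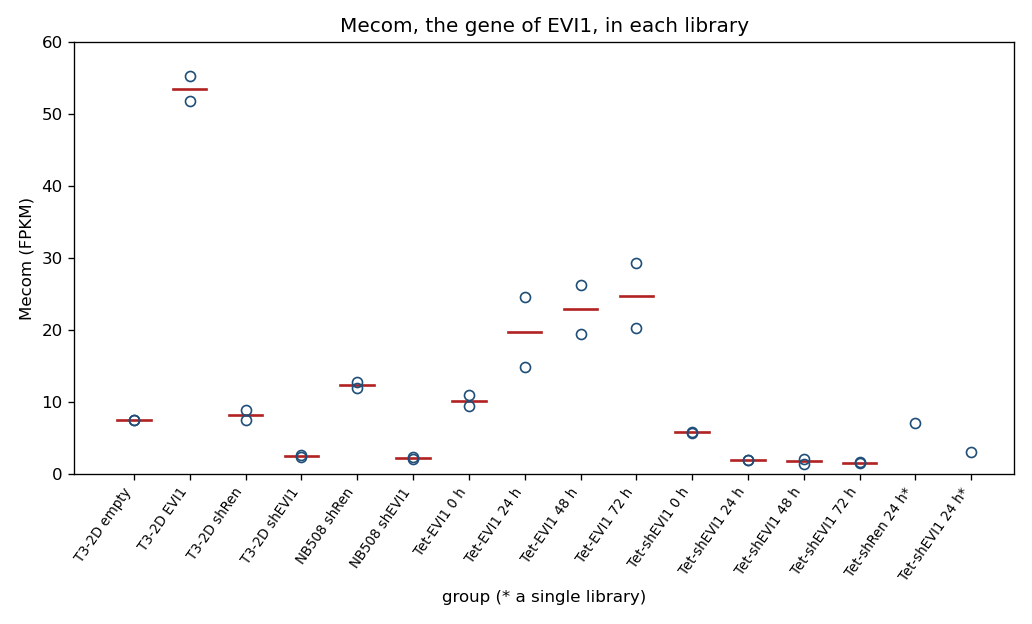
Mecom in FPKM (vertical axis) in each library (circles) by group (horizontal axis), with the group mean as a line; groups come from 6 separately normalised tables. Stable EVI1 reached 51.8 and 55.3 FPKM, while shEVI1 groups other than Tet-shEVI1 at 0 h (5.81 and 5.63) lay between 1.38 and 2.57 and the single Tet-shEVI1 library at 3.

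With stable EVI1, among the largest changes in T3-2D cells were rises of Ivl, Aqp5, Dmbt1 and Mapk13 and falls of Serpina1b, Habp2 and Akap12. Ivl (involucrin, of the cornified envelope) rose from 1.76 ± 0.234 to 49.4 ± 1.17 FPKM (SD, n = 2 each; log2 fold change 4.19, adjusted p = 5.07e-09). Sprr1a, another cornified envelope precursor, went from 54.7 ± 0.965 to 640.4 ± 56.4. The water channel Aqp5 rose from 2.32 ± 0.0391 to 48.6 ± 0.420, the mucosal defence protein Dmbt1 from 0.532 ± 0.241 to 21.5 ± 0.262, and the stress kinase gene Mapk13 from 0.322 ± 0.0309 to 15.4 ± 2.29. Fgfbp1 (3.48 on the log2 scale), the cytokine Il1a (3.43) and the chitinase-like Chil1 (3.34) also rose. The protease inhibitor Serpina1b fell from 40.4 ± 1.87 to 0.130 ± 0.0120 (log2 fold change -5.19, adjusted p = 3.06e-09), and Serpina1a, Serpina1c and Serpina1d fell by 4.33, 4.06 and 3.61. Reads could be split among these near-identical copies. Habp2 (a plasma protease) fell by 4.35, Akap12 (a kinase scaffold) by 4.25, Gc (vitamin D binding protein) by 3.74 and Sparc (a matrix protein) by 3.40. Usp16 was listed at 0 and 0 with empty vector and at 14.1 and 15 with EVI1, and S100a9 at 0 and 0 against 10.7 and 11.0. Surf2 was listed at 33.9 and 33.5 with empty vector and at 0 and 0 with EVI1, and Iah1 at 15 and 13.4 against 0 and 0.

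The hypoxia and glycolysis list rose as a whole: 28 of its 28 measured members passed upward, also when adjusted over the list alone. Car9, a carbonic anhydrase induced by hypoxia, went from 3.93 ± 0.0692 to 28.8 ± 0.195 FPKM, and Slc16a3 (lactate export), Egln3 and Ero1l rose by 1.84, 1.85 and 2.01 on the log2 scale. Camera gave adjusted p = 1.06e-13 for this list at its preset correlation, and adjusted p = 0.416 with an estimated correlation. Of 21 epithelial genes 20 rose and 0 fell, among them Epcam (4.88 ± 0.273 to 32.8 ± 0.423), Krt19 (899 ± 39.7 to 2296 ± 113), Cldn3 (1.95) and Cldn7 (2.01), with camera adjusted p = 2.17e-09 and adjusted p = 0.416 with an estimated correlation. Classical PDA markers rose in 15 and fell in 2 of 19, led by Anxa10 (28.4 ± 0.105 to 111 ± 3.52), Elf3 (2.01), Ctse (1.87) and Lgals4 (1.40). Basal-like markers rose in 6 and fell in 1 of 9, with Sprr1a, Fgfbp1, Tns4 (2.87) and the glucose transporter Slc2a1 (1.12). Camera gave adjusted p = 8.83e-07 and 0.000815 for these subtype lists, each with adjusted p = 0.416 with an estimated correlation. Cholesterol synthesis genes rose in 21 and fell in 1 of 24 (Tm7sf2 1.42, Cyp51 0.92, Msmo1 0.84, Sc5d 0.80). Its camera adjusted p was 4.05e-08, and adjusted p = 0.44 with an estimated correlation.

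S and G2/M phase genes fell in 32 and rose in 1 of 34, as in Ccna2 (cyclin A2, 105 ± 3.01 to 43.2 ± 0.942 FPKM), Birc5 (-1.01), Plk1 (-1.18) and Cenpe (-1.30). Camera adjusted p was 2.17e-09, and adjusted p = 0.416 with an estimated correlation. YAP targets fell in 15 and rose in 0 of 17, with Ankrd1 from 411 ± 5.66 to 119 ± 2.15, Axl (-1.75), Cyr61 (-1.58) and Amotl2 (-1.50). Here camera gave adjusted p = 2.72e-05, and adjusted p = 0.416 with an estimated correlation. The NF-kappaB and cytokine list split, with 19 of 27 up and 6 down. Lcn2 (lipocalin, an iron-binding antimicrobial protein) rose from 29.2 ± 1.04 to 274 ± 15.6 and Ptgs2 by 1.79, while the monocyte attractant Ccl2 fell by 3.29 and Csf1 by 2.11. MAPK output genes rose in 15 and fell in 5 of 23 (Fos 2.53, Egr1 1.93, Ier3 1.62), p53 targets in 12 and 5 of 20 (Cdkn1a 2.06, Tnfrsf10b 1.96, Perp 1.48), EGF family genes in 7 and 2 of 9 (Erbb3 2.85, Egfr -0.79) and NRF2 genes in 12 and 6 of 21 (Gsta1 1.82, Gclm -1.24). Secreted proteases and their partners rose in 14 and fell in 6 of 20, with Mmp13 from 40.3 ± 2.16 to 191 ± 0.691 and Mmp3 up by 2.60. Camera adjusted p was 7.37e-05 for NF-kappaB, 0.00101 for MAPK, 0.00207 for p53, 0.0125 for the EGF family, 0.0174 for NRF2 and 0.0041 for proteases. None passed with an estimated correlation, where adjusted p = 0.416 or 0.44.

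Mesenchymal genes were not called as a list (7 up, 9 down of 17, camera adjusted p = 0.768). Its median (-0.20) and mean (-0.05) lay below 0 while camera pointed up (median and mean also differ in sign for interferon, 0.12 and -0.02, and foregut factors, -0.05 and 0.19), and Sparc and Axl (-1.75) fell as Mmp3 and Mmp14 (0.80) rose. Foregut factors moved both ways (6 up, 5 down of 14, adjusted p = 0.372), with Klf5 up by 0.98, Klf4 by 1.17 and Hhex down by 0.76. Camera did not call reported EVI1 targets (5 up, 4 down of 12, adjusted p = 0.294) or PRDM factors and corepressors (1 up, 7 down of 12, 0.243). Nor did it call interferon (6 up, 5 down of 14, 0.643), TGF-beta response (6 up, 12 down of 20, 0.212), Wnt and Notch targets (5 up, 3 down of 10, 0.293), ATF4 and unfolded protein response (12 up, 9 down of 30, 0.113), hemidesmosome and integrins (9 up, 4 down of 17, 0.0911), ribosomal proteins (6 up, 6 down of 43, 0.395) or histones (2 up, 5 down of 9, 0.595). The counts for these 13 called and 11 uncalled lists were the same when adjusted over the list alone, except ribosomal proteins (4 up, 4 down).

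In limma's test 2862 genes were higher and 4147 lower of 10613, of which 530 and 289 changed by 2-fold or more. The split depends on scaling, with 3136 higher and 3826 lower after quantile normalisation and 3438 and 3460 with a size factor. The median change of all genes was -0.07 on the log2 scale. Simulated data with 50 genes changed at each fold size gave 8.97% false calls. With 7009 genes called in the real fit, that share cannot be carried over to these calls.

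Loss of EVI1 in T3-2D cells gave some of its largest falls in Saa3, C3 and Lcn2 and largest rises in Prl2c2 and Prl2c4. Lcn2 fell from 530.3 ± 9.44 FPKM with shRen to 63.1 ± 42.0 with shEVI1 (SD, n = 2 each; log2 fold change -3.22, adjusted p = 0.00400). The acute-phase protein Saa3 fell from 34.9 ± 1.80 to 2.08 ± 2.31, complement C3 from 172 ± 17.8 to 14.9 ± 11.1 and complement C1s1 from 24.3 ± 1.82 to 2.36 ± 1.74. The surface proteins Ly6a (98.7 ± 6.32 to 16.6 ± 4.22, adjusted p = 0.000791) and Ly6c1 (-2.62), whose reads could be shared, fell along with Alpl (-2.68) and Pdzk1ip1 (-2.40). Prl2c2 (proliferin) rose from 128 ± 10.3 to 732 ± 222 (log2 fold change 2.48, adjusted p = 0.00151), next to Prl2c4 (2.40), Prl2c5 (2.22) and Prl2c1 (1.91). The copies of this family are near-identical. Cardiac troponin Tnnt2 rose from 22.1 ± 4.43 to 105 ± 22.0, the hyaluronan synthase Has2 from 2.36 ± 0.529 to 11.1 ± 3.21 and the peptide gene Uts2b from 0.936 ± 0.0377 to 7.89 ± 5.31. Klra18, in a cluster of similar receptors, rose by 2.20. Slirp was listed at 0 and 0 with shRen and 79.9 and 69.7 with shEVI1, Ccdc77 at 0 and 0 against 10.2 and 8.90, Bri3 at 23.9 and 24.8 against 0 and 0, and Tmem150a at 7.65 and 8.04 against 0 and 0. In T3-2D shEVI1 vs shRen without T3-2D shRen replicate 1, Lcn2 and Saa3 had limma adjusted p = 0.0509, and without replicate 2 Lcn2, Saa3 and C3 had 0.0521. Uts2b and Alpl passed under neither (0.114 and 0.0659, then 0.104 and 0.0672), while Mecom, Prl2c2, Tnnt2 and Ly6a passed under both.

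The NF-kappaB and cytokine list fell in 11 and rose in 1 of 26 (15 down and 2 up adjusted over the list alone), with Ccl20 from 71.0 ± 1.47 to 37.4 ± 0.774 FPKM, Csf1 (-1.26) and Cxcl2 (-1.06) beside Lcn2. Camera adjusted p was 2e-04, and adjusted p = 0.607 with an estimated correlation. Cholesterol synthesis genes rose in 8 and fell in 0 of 24 (14 and 0 over the list alone), among them Fdps (0.65), Nsdhl (0.66), Idi1 (0.54) and Tm7sf2 (0.54). For that list camera gave adjusted p = 3.29e-12, and adjusted p = 0.605 with an estimated correlation. YAP targets fell in 7 and rose in 2 of 17 (8 and 2 over the list alone; Amotl2 -1.13, Ptpn14 -0.88, Wwc1 -0.82; camera adjusted p = 0.0278, and adjusted p = 0.61 with an estimated correlation). Ribosomal proteins rose in 2 and fell in 0 of 43 (0 over the list alone; Rpl12 0.41, Rpl32 0.38; adjusted p = 5.10e-11, and adjusted p = 0.605 with an estimated correlation). Smaller splits passed camera for MAPK output (1 up, 2 down of 23, adjusted p = 0.00347), hemidesmosome and integrins (2 up, 1 down of 16, and 5 up, 3 down adjusted over the list alone, 0.0110; Itga6 0.78, Itgav -0.53) and mesenchymal genes (3 up, 2 down of 16, and 5 up, 2 down over the list alone, 0.0240; Vim 0.78, Itga5 0.65, Sparc -0.70). They had adjusted p = 0.605 to 0.607 with an estimated correlation.

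Camera did not call classical PDA markers (5 up, 2 down of 16, and 5 up, 3 down adjusted over the list alone, adjusted p = 0.0613), where Spink4 fell by 1.97 and Anxa10 (1.18), Krt20 (0.94) and Ctse (0.89) rose. Epithelial genes moved both ways (3 up, 3 down of 18, and 4 up, 5 down over the list alone, 0.795), with Krt8 and Krt19 up by 0.55 and 0.59 and Cldn7 and Cldn3 down by 0.75 and 1.00. Secreted proteases did too (7 up, 5 down of 20, and 8 up, 6 down over the list alone, 0.0771; Serpinb5 1.65, Adamts1 -1.64). The EGF family showed 3 up and 0 down of 9 (4 and 1 over the list alone, 0.0526; Areg 1.00, Btc 0.98), interferon genes 0 up and 3 down of 13 (0 and 6 over the list alone, 0.0593; Gbp2 -1.65), TGF-beta response 4 up and 2 down of 21 (0.189; Tgfb2 -1.64, Thbs1 -1.31), p53 targets 2 up and 2 down of 19 (0.795; Fas -2.09) and NRF2 genes 0 up and 3 down of 21 (2 and 4 over the list alone, 0.833; Gsta3 -1.65). Hypoxia (0 up, 1 down of 28, 0.0911), cell cycle (3 up, 1 down of 34, and 4 up, 4 down over the list alone, 0.362), EVI1 targets (3 up, 3 down of 12, and 3 up, 4 down over the list alone, 0.993; Adgrg1 -1.15), basal-like markers (1 up, 0 down of 8, and 2 up, 1 down over the list alone, 0.362) and Wnt and Notch targets (2 up, 2 down of 11, 0.461) were not called. Limma passed 0 members of the PRDM (0.461), foregut (0.0771), ATF4 (0.623) and histone (0.553) lists over all genes, where 2555 genes lay at an unadjusted p under 0.05, and 2 foregut members passed upward over the list alone. Camera pointed up for the PRDM, epithelial, cell cycle, TGF-beta, Wnt and Notch, hypoxia, p53, NRF2 and protease lists, though the mean of each lay below 0.

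Limma's test called 292 genes higher and 574 lower of 10586, with 58 and 156 changed by 2-fold or more. The split depends on scaling: quantile normalisation gave 401 higher and 375 lower, and a size factor 436 and 447. The count was 80 without shRen replicate 1, 91 without shRen replicate 2, and 93 with no filter on low values.

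Whether loss mirrored gain in T3-2D cells was tested over 10360 genes. Lcn2 (3.19 with EVI1, -3.22 with shEVI1), Ly6a (3.33, -2.52), Pdzk1ip1 (2.54, -2.40), Ly6c1 (2.23, -2.62), the peptidoglycan receptor Pglyrp1 (2.67, -1.74) and C3 (1.63, -3.64) rose with EVI1 and fell with shEVI1. Tnnt2 (-1.72, 2.20), Glrp1 (-2.28, 1.45), Lect2 (-1.65, 1.33) and the galectin Lgals2 (-0.94, 1.45) went the other way. Genes up with EVI1 and down with shEVI1 numbered 156 against 135 expected of independent lists (Fisher's exact test p = 0.0312, adjusted p = 0.0416), and genes down with EVI1 and up with shEVI1 numbered 73, fewer than the 112 expected (p = 7.17e-07). Same-direction sets were larger than expected. They held 154 genes up in both against 72.9 (Fisher's exact test p = 4.46e-25), such as Acan (1.97, 1.67), Serpinb5 (1.86, 1.65), Capg (1.98, 1.24) and Prl2c4 (1.73, 2.40). Another 273 were down in both against 208 (exact p = 3.72e-09), such as Akap12 (-4.25, -2.03), Fgfr2 (-3.12, -1.90), Wisp1 (-3.29, -1.65) and Fscn1 (-2.74, -1.67).

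Among calls of 2-fold or more, a setting added after seeing the data, 37 genes went up with EVI1 and down with shEVI1 against 5.27 expected (exact p = 8.07e-22), 16 went up in both (2.20 expected, p = 2.28e-10) and 42 down in both (3.51 expected, p = 1.82e-34). The 156 became 114 with quantile normalisation (exact p = 0.0605) and 135 with a size factor (p = 0.271). It was 132 without EVI1 replicate 2 (exact p = 0.0726) and 125 without the unnumbered shEVI1 library (p = 0.0793). With no filter on low values the 156 became 21 against 12.7 expected (exact p = 0.0166) and the 154 became 14 against 6.06 (p = 0.000924). The 73 became 4 against 8.15 (exact p = 0.0991) and the 273 became 25 against 17.1 (p = 0.0315). Among fits with 1 library left out, the counts fell most without a shRen library. Without shRen replicate 1 the 156 became 24 against 12.5 expected (exact p = 0.000425), the 154 became 17 against 7.16 (p = 8.69e-05), the 73 became 8 against 11.1 (p = 0.251) and the 273 became 21 against 19.5 (p = 0.663). Without shRen replicate 2 they became 14 against 8.42 (exact p = 0.0426), 31 against 14.0 (p = 1.17e-06), 12 against 21.9 (p = 0.00558) and 19 against 13.1 (p = 0.0487).

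**Figure D2:**
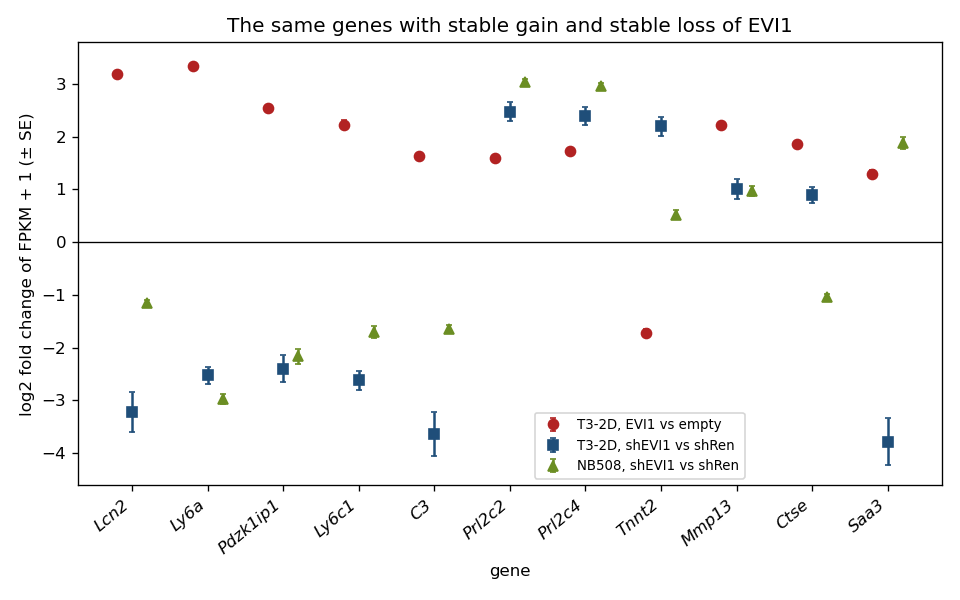
Log2 fold change of FPKM + 1 (vertical axis; bars are limma's SE) of named genes (horizontal axis) in T3-2D with EVI1 (circles), T3-2D with shEVI1 (squares) and NB508 with shEVI1 (triangles). Lcn2, Ly6a, Pdzk1ip1, Ly6c1 and C3 lie above 0 with EVI1 and below 0 with both knockdowns, and Prl2c2, Prl2c4 and Mmp13 lie above 0 in each.

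In NB508 cells loss of EVI1 gave some of its largest rises in Prl2c2 and Prl2c4 and largest falls in Ly6a and Tff2. Aldh1l2 (mitochondrial folate metabolism) rose from 8.03 ± 0.0212 to 35.7 ± 0.445 FPKM (SD, n = 2 each; log2 fold change 2.02, adjusted p = 1.05e-07) and Cth (cysteine synthesis) from 6.00 ± 0.346 to 26.7 ± 1.73. Prl2c2 rose from 32.7 ± 1.26 to 275 ± 2.93 (log2 fold change 3.03, adjusted p = 1.76e-09), with Prl2c4 (2.97) and Prl2c5 (2.34). The intestinal cadherin Cdh17 rose by 2.17 and the glycerol channel Aqp9 by 2.22. Ly6a fell from 70.2 ± 0.940 to 8.17 ± 1.41 and the trefoil factor Tff2 from 37.8 ± 6.63 to 4.78 ± 0.863. Syt8 (-2.55), Apoc2 (-2.53), Pcp4l1 (-2.32), the protease Adamts1 (-2.19) and Pdzk1ip1 (-2.16) fell too. Ppat was listed at 0.1 and 0.1 with shRen and 11.7 and 12.4 with shEVI1, Pigf at 0.1 and 0.1 against 12.3 and 11.4, and Tor1aip1 at 0.1 and 0.1 against 8.39 and 10.3. Glt8d1 was listed at 14.2 and 13.3 against 0.1 and 0.1, and Abcd1 at 5.85 and 5.06 against 0.1 and 0.1.

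The ATF4 and unfolded protein response list rose in 27 and fell in 1 of 32, with Psph (17.0 ± 0.474 to 53.7 ± 2.31 FPKM), Trib3 (1.54) and Ddit3 (32 ± 4.87 to 90.2 ± 2.31) beside Aldh1l2. Camera adjusted p was 8.18e-14, and adjusted p = 0.321 with an estimated correlation. Cell cycle genes rose in 28 and fell in 0 of 34, with the replication licensing genes Mcm2 (0.90), Mcm4 (0.83) and Mcm7 (0.84) and Pcna (0.78). Its camera adjusted p was 1.04e-09, and adjusted p = 0.456 with an estimated correlation. NF-kappaB and cytokine genes fell in 17 and rose in 3 of 26 (18 and 3 over the list alone), with Lcn2 down by 1.16, Icam1 by 0.89 and Nfkbiz by 0.78 and Saa3 up by 1.88. Classical PDA markers fell in 15 and rose in 3 of 19 (Muc1 -1.04, Ctse -1.03), epithelial genes in 13 and 1 of 17 (Tjp3 -0.93, Epcam -0.81, Cdh1 -0.50) and TGF-beta response genes in 10 and 0 of 20 (Thbs1 -1.51, Ltbp2 -1.19, Ctgf -0.82). Camera gave adjusted p = 6.33e-06 for NF-kappaB, 0.00014 for classical, 0.00014 for epithelial and 0.000577 for TGF-beta genes. These were adjusted p = 0.321, 0.321, 0.348 and 0.321 with an estimated correlation.

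Hypoxia and glycolysis genes fell in 14 and rose in 2 of 28 (Car12 -0.91, Pdk1 -0.53; camera adjusted p = 0.000799, and adjusted p = 0.456 with an estimated correlation). Basal-like markers fell in 6 and rose in 1 of 9, led by the keratin Krt7 (259 ± 11.7 to 65.2 ± 7.38) and Tns4 (-1.57), with camera adjusted p = 0.00622 and adjusted p = 0.348 with an estimated correlation. Hemidesmosome and integrin genes fell in 10 and rose in 2 of 16 (Lamb3 -0.86, Itgb4 -0.85, Itgav -0.83; 0.00622), YAP targets in 6 and 1 of 17 (Cyr61 -1.14, F3 -1.05; 0.0164), interferon genes in 6 and 1 of 15 (0.0210), cholesterol genes in 10 and 2 of 22 (11 and 2 adjusted over the list alone; 0.0163) and NRF2 genes in 10 and 3 of 18 (10 and 4 over the list alone; Aldh3a1 -0.88; 0.0496). The same lists had adjusted p = 0.456, 0.483, 0.456, 0.617 and 0.617 with an estimated correlation.

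Camera did not call EVI1 targets (2 up, 4 down of 12, adjusted p = 0.497; Adgrg1 -1.45, Bcat1 1.48), foregut factors (3 up, 7 down of 15, 0.470; Foxa1 1.17, Sox9 0.69, Pdx1 -0.70), mesenchymal genes (6 up, 5 down of 18, and 7 up, 5 down adjusted over the list alone, 0.916; S100a4 -1.05, Snai2 0.81) or the EGF family (3 up, 2 down of 9, and 3 up, 4 down over the list alone, 0.916; Areg 0.95; median -0.17, mean 0.04). MAPK output (6 up, 8 down of 24, and 6 up, 9 down over the list alone, 0.542; Il11 -2.07), p53 targets (7 up, 7 down of 20, and 7 up, 8 down over the list alone, 0.916), Wnt and Notch targets (1 up, 4 down of 10, and 1 up, 5 down over the list alone, 0.222), proteases (1 up, 6 down of 17, 0.135), ribosomal proteins (6 up, 2 down of 43, and 2 up, 0 down over the list alone, 0.390), PRDM factors (1 up, 1 down of 13, 0.870) and fibroblast markers (2 up, 1 down of 5, 0.916; median -0.15, mean 0.13) were not called either. In limma's test 2299 genes were higher and 2101 lower of 10688, with 87 and 135 changed by 2-fold or more.

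**Figure D3:**
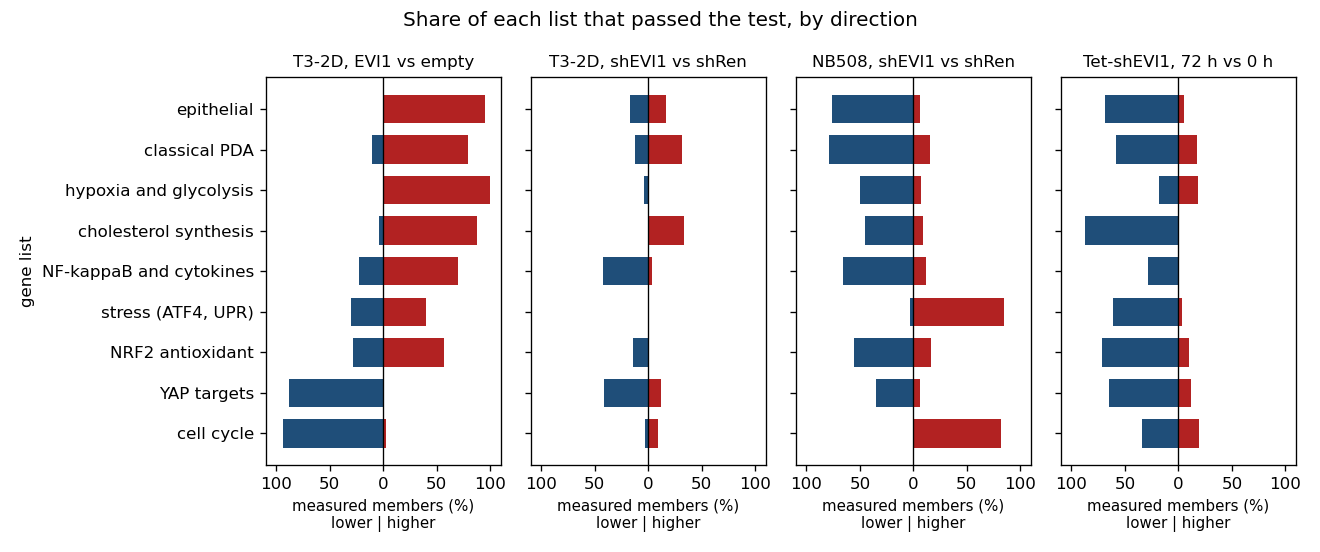
Percent of the measured members of each gene list (rows) that passed limma's test upward (right of 0) or downward (left of 0) in 4 comparisons. Hypoxia genes are higher in 28 of 28 with stable EVI1, cell cycle genes are lower in 32 of 34 there and higher in 28 of 34 with shEVI1 in NB508; with a size factor or quantile normalisation the split of all calls moves toward even in T3-2D shEVI1 and Tet-shEVI1.

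By the labels, the knockdowns of T3-2D and NB508 used the same hairpins against EVI1. Effects of these hairpins apart from EVI1 could therefore be shared by the lines too. The knockdowns of both lines shared 241 genes that fell against 94.9 expected over 10149 genes (Fisher's exact test p = 2.13e-52). These included Ly6a (-2.52 in T3-2D, -2.97 in NB508), Pdzk1ip1 (-2.40, -2.16), complement factor Cfi (-1.76, -1.90), C3 (-3.64, -1.64), Adamts1 (-1.64, -2.19), the oxidase subunit Cybb (-1.54, -1.47) and thrombospondin Thbs1 (-1.31, -1.51). Genes up in both numbered 68 against 55.5 (exact p = 0.0645), such as Prl2c2 (2.48, 3.03), the collagenase Mmp13 (1.01, 0.96), the EGF ligand Areg (1.00, 0.95) and Igfbp3 (0.86, 0.90). A further 84 genes rose in T3-2D and fell in NB508 (47.9 expected, exact p = 5.32e-08), and 59 went the reverse way (110 expected, p = 2.47e-09). The 68 became 92 against 82.9 expected with a size factor (exact p = 0.257) and 87 against 72.4 with quantile normalisation (exact p = 0.0515). With genes at the floor left out it was 71 against 56.4 (exact p = 0.0323). Its odds ratio was 1.32 with all libraries. With 1 library left out the odds ratio ran from 1.20, without the unnumbered T3-2D shEVI1 library, to 3.03, without T3-2D shRen replicate 1. The 84 became 7 (exact p = 0.191) without T3-2D shRen replicate 1, and the 59 became 4 (p = 0.372) without shRen replicate 2 and 73 (p = 0.0503) without the unnumbered shEVI1 library. The 241 became 34 and 21 without shRen replicate 1 and 2.

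Limma's test of the difference between the knockdown effects passed for 2465 of 10150 genes, 884 with the larger value in T3-2D and 1581 with the larger in NB508. That split was 1202 and 1199 with quantile normalisation and 1218 and 1210 with a size factor. Of the 2465, 143 were called in both lines with opposite signs. Saa3 fell by 3.78 in T3-2D and rose by 1.88 in NB508, Has2 rose by 1.84 and fell by 1.20, and Ctse rose by 0.89 and fell by 1.03 (genes chosen after their values were seen, apart from the named set). The count of 2465 became 1466 without T3-2D shRen replicate 1. Without shRen replicate 1, shRen replicate 2, the first or the second hairpin of NB508 it became 1491, 1235, 1257 or 1397.

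In Tet-EVI1 cells no gene passed the test at any time, and the following are values only. Wnt7a (a Wnt ligand) read 1.16 ± 0.580 FPKM at 0 h and 3.95 ± 0.816, 5.84 ± 0.210 and 11.2 ± 5.59 at 24, 48 and 72 h (SD, n = 2 each; adjusted p at 72 h 0.227). The adhesion gene Mpzl2 read 2.12, 6.67, 9.43 and 12.3 at the same times. Clca3b read 93.4, 41.2, 29.5 and 12.7, Tm4sf20 13.3, 2.73, 3.23 and 1.59, and the microvillus protein Vil1 31.3, 9, 7.83 and 6.67. Alpl, Gzme, Uts2b and Serpinb1a had mean log2 changes of -1.90, -1.97, -1.91 and -2.16. Fgfbp1 differed between the 72 h libraries (6.17 and 58.9), as did Mt2 (49.4 and 584) and Hist2h2ac (27.6 and 4.11). Cdc37l1 was listed at 0 and 0 at 0 h, 11.5 and 11.1 at 24 h, 0 and 11.7 at 48 h and 15.4 and 0 at 72 h.

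Replication histone messages, which lack a poly(A) tail, had a median log2 change of 1.76 at 72 h, made up of 2.27 in replicate 1 and 0.99 in replicate 2 (Hist1h2bf 27.9 and 1.83 FPKM). Of 22 members 0 passed over all genes and 12 passed upward adjusted over the list alone (camera adjusted p = 1.38e-25, and adjusted p = 0.33 with an estimated correlation). Also adjusted over the list alone, 2 Wnt and Notch, 1 classical and 1 basal-like member passed upward and 2 NRF2, 1 classical and 1 hemidesmosome member downward at 72 h, and 0 in the remaining lists and times. Camera also called cholesterol (adjusted p = 7.52e-11), hypoxia (3.14e-06), ribosomal proteins (2.06e-06), ATF4 (2.96e-05), p53 (8.76e-05), epithelial (0.000179), MAPK (0.000251), Wnt and Notch (0.00278) and EGF family genes (0.0115) upward and cell cycle genes downward (3.40e-05) at 72 h. They had adjusted p = 0.33 to 0.605 with an estimated correlation. At 24 h hypoxia genes were called downward (median -0.54, 7.80e-06) and cell cycle (0.00508) and ribosomal proteins (0.00178) upward, with adjusted p = 0.991 with an estimated correlation. At 48 h histones (3.59e-10), p53 (0.00221) and ribosomal proteins (0.0127) were called upward and hypoxia (0.00153), mesenchymal (0.0127) and NRF2 genes (0.0140) downward, with adjusted p = 0.49 to 0.955 with an estimated correlation. The 72 h replicate 2 library stood apart in these lists: its change from 0 h had a median of 1.42 for hypoxia and -1.29 for cell cycle genes, against -0.34 and -0.05 in 72 h replicate 1.

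Limma called 0 of 10612 genes at 24, 48 and 72 h and at any time, with 157, 180, 795 and 232 at an unadjusted p under 0.05. Without 72 h replicate 1 the count at 72 h was 3201 (1806 at any time), and without 72 h replicate 2 it was 1. Genes called up with stable EVI1 had a median log2 change of 0.13 at 72 h against -0.17 for all genes (camera p = 5.44e-22, and p = 0.0721 with an estimated correlation), and those called down -0.37 (p = 7.39e-17, and p = 0.204 with an estimated correlation). Left without 72 h replicate 2, these sets had camera p = 0.520 and 0.599 at the preset correlation. At 24 h the same sets moved the other way, with medians of -0.11 for genes called up and 0.02 for those called down against -0.03 for all genes (camera p = 0.00246 and 0.00266, and p = 0.489 and 0.614 with an estimated correlation). At 48 h neither set passed camera at the preset correlation (p = 0.481 and 0.706). With a size factor or quantile normalisation the median of all genes at 72 h was -0.02.

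**Figure D4:**
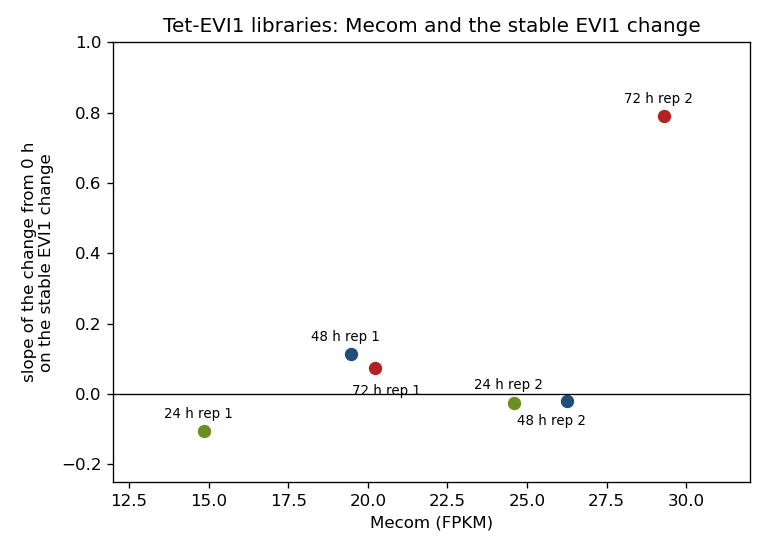
Slope, across genes, of the change from 0 h on the change with stable EVI1 (vertical axis, no unit) against Mecom in FPKM (horizontal axis) in the 6 induced Tet-EVI1 libraries. The 72 h replicate 2 library lies at 0.79 with Mecom at 29.3, and the other 5 lie between -0.11 and 0.11 with Mecom from 14.9 to 26.2.

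In Tet-shEVI1 cells the developmental factor gene Pax9 and the adhesion receptor gene Adgrg1 were higher after doxycycline, and Sprr1a, Ptgds and Gsta1 were lower. All libraries of this series carry the same hairpin, and no control hairpin was followed over time. Effects of doxycycline, of time in culture or of the hairpin itself therefore cannot be separated from loss of EVI1. Pax9 went from 2.77 ± 0.0615 FPKM at 0 h to 9.58 ± 0.312, 11.4 ± 0.451 and 12.7 ± 0.401 at 24, 48 and 72 h (SD, n = 2 each; log2 fold change 1.86 and adjusted p = 9.70e-08 at 72 h). Adgrg1 rose by 1.51, 1.40 and 1.70 at the 3 times, the endosome tether Eea1 from 11.6 ± 0.0196 to 28.8 ± 0.375 and the nucleoside transporter Slc29a3 from 3.35 ± 0.382 to 8.70 ± 0.508. In the stable knockdowns of T3-2D and NB508, by contrast, Adgrg1 fell. Megf10, Ms4a4b, Mndal, the metallothionein Mt2 and Chic2 rose by a mean of 1.44, 1.27, 1.25, 1.11 and 0.76 over the 3 times. The cell cycle inhibitor Cdkn1a was highest at 24 h, at 9.78 ± 0.361 from 3.13 ± 0.174. Sprr1a fell from 182 ± 7.53 through 79.7 and 53.7 to 32.4 ± 3.20 (log2 fold change -2.45, adjusted p = 3.48e-08 at 72 h). Ptgds (prostaglandin D synthase) fell from 12.3 ± 0.638 to 1.47 ± 0.630 at 24 h, and the glutathione transferase Gsta1 from 44.6 ± 1.52 to 15 ± 0.0559. Aqp5 fell from 7.03 to 1.92 at 72 h, and Timp3, S100a4, Hspa1b, Prr15l and Gngt2 fell by a mean of 1.37, 1.29, 1.18, 1.17 and 1.13.

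**Figure D5:**
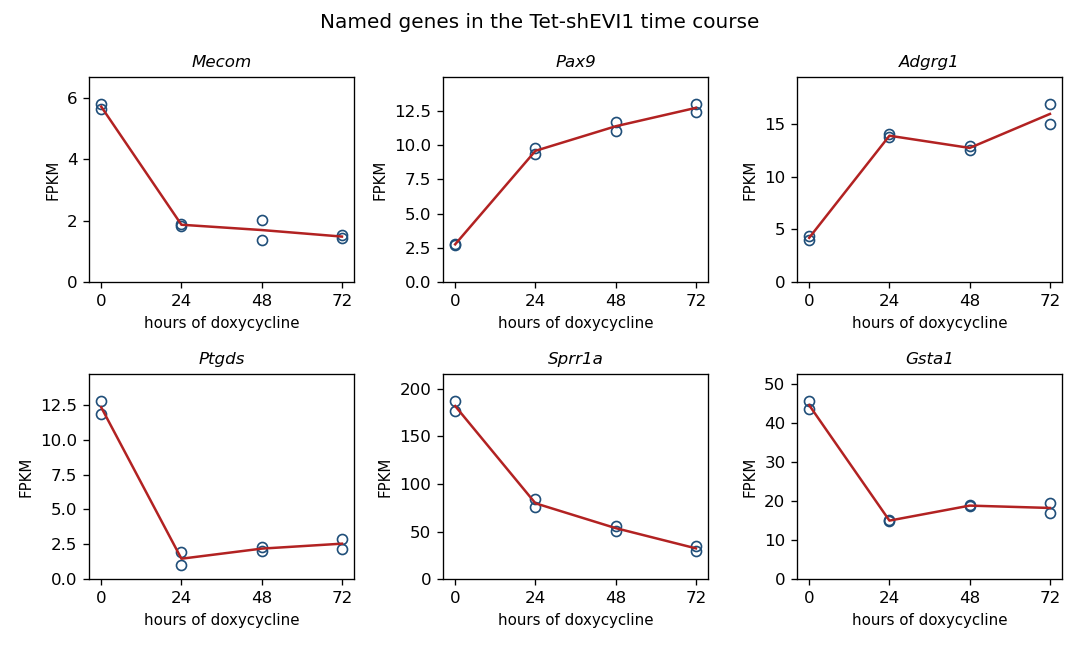
FPKM (vertical axis) at 0, 24, 48 and 72 h of doxycycline (horizontal axis) in Tet-shEVI1 cells; circles are libraries and lines join the means. Mecom, Ptgds, Sprr1a and Gsta1 are lower and Pax9 and Adgrg1 higher at each time after 0 h.

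Cholesterol synthesis genes fell at all 3 times, in 17, 20 and 21 of 24 with 0 rising (19, 20 and 22 over the list alone; at 72 h Pmvk -0.65, Mvd -0.56, Msmo1 -0.44). With the stable knockdown they went the other way in T3-2D (8 up, 0 down of 24) but fell in NB508 (2 up, 10 down of 22). In Tet-shEVI1 the list's values with camera were as follows. Camera adjusted p was 7.60e-05, 2.68e-06 and 8.40e-09, and adjusted p = 0.255, 0.187 and 0.178 with an estimated correlation. NRF2 genes fell in 11, 14 and 15 of 21 and rose in 0, 0 and 2 (14, 14 and 16 down and 1, 1 and 2 up over the list alone), including Gsta1 and the pentose phosphate enzymes Pgd (-0.56) and G6pdx (-0.54). Epithelial genes fell in 12, 12 and 13 of 19 and rose in 1 at each time (13, 14 and 15 down over the list alone; Cldn7 -0.89, Cldn3 -0.82). Camera adjusted p was 4.75e-05, 0.000211 and 0.000566 for NRF2 and 0.000345, 0.00122 and 0.00256 for epithelial genes. With an estimated correlation adjusted p = 0.124, 0.170 and 0.178 in both. Hypoxia genes rose in 19, 6 and 5 of 27 and fell in 1, 2 and 5 (21, 7 and 5 up and 2, 2 and 5 down over the list alone; Bnip3 0.89 at 24 h), with camera adjusted p = 2.95e-13, 2.68e-06 and 0.137. The hypoxia list had adjusted p = 0.123 at 24 h and 0.170 at 48 h with an estimated correlation.

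ATF4 and unfolded protein response genes split evenly at 24 h (6 up, 6 down of 31; 8 and 7 over the list alone), then fell in 15 and 19 and rose in 1 and 1 at 48 and 72 h (15 and 21 down over the list alone; Nupr1 -0.90, Phgdh -0.60, Hspa5 -0.44), with camera adjusted p = 0.135, 0.00236 and 0.000419. With an estimated correlation adjusted p = 0.265 at 48 h and 0.178 at 72 h. Ribosomal proteins fell in 30, 24 and 13 of 43 (37, 30 and 13 over the list alone; 2.83e-07, 0.000211 and 0.256), with adjusted p = 0.465 and 0.686 with an estimated correlation at 24 and 48 h. YAP targets fell in 9, 9 and 11 of 17 and rose in 0, 2 and 2 (1, 2 and 2 up over the list alone; 0.0238, 0.0211 and 0.0258; Ankrd1 -0.76, Ctgf -0.58), with adjusted p = 0.465 to 0.533 with an estimated correlation. Mesenchymal genes rose in 7, 8 and 8 of 15 and fell in 3, 4 and 3 (8, 8 and 8 up over the list alone; 0.00551, 0.000944 and 0.00106; Vim 0.44, Loxl2 0.60, Cdh2 0.44, S100a4 -1.25). Hemidesmosome and integrin genes rose in 8, 4 and 6 of 16 and fell in 2, 2 and 3 (9, 5 and 6 up over the list alone; 3.05e-05, 0.000944 and 0.0102; Cd44 0.59). Mesenchymal genes had adjusted p = 0.28 to 0.355 and hemidesmosome genes 0.346 to 0.517 with an estimated correlation. At 24 h cell cycle genes rose in 9 and fell in 3 of 32 (10 and 5 over the list alone; 0.00468) and foregut factors fell in 7 and rose in 1 of 15 (8 and 1 over the list alone; 0.0238; Sox17 -1.13), with adjusted p = 0.368 and 0.255 with an estimated correlation. EVI1 targets rose in 4 and fell in 2 of 12 at 24 h (0.0238) and in 3 and 2 at 48 h (4 and 3 over the list alone; 0.0425), with adjusted p = 0.383 and 0.533 with an estimated correlation. Camera called none of the PRDM, classical, basal-like, EGF family, MAPK, interferon, NF-kappaB, TGF-beta, Wnt and Notch, p53, protease and histone lists at any time. At 72 h limma passed 0 up and 2 down of 13 PRDM genes (0 and 1 adjusted over the list alone), 3 and 10 of 17 classical markers, 2 and 5 of 9 basal-like markers (2 and 6 over the list alone), 1 and 3 of 9 EGF family genes (1 and 5), 3 and 12 of 22 MAPK genes (4 and 13), 0 and 2 of 12 interferon genes, 0 and 6 of 21 NF-kappaB genes, 3 and 6 of 19 TGF-beta genes (4 and 6), 1 and 2 of 8 Wnt and Notch targets (1 and 5), 2 and 7 of 18 p53 targets (2 and 8), 2 and 6 of 17 proteases and 1 and 2 of 15 histones.

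Limma called 804 genes higher and 2221 lower of 10508 at 24 h, 585 and 2829 at 48 h, and 773 and 2864 at 72 h, of which 39, 29 and 39 changed by 2-fold or more. The direction depends on scaling, since quantile normalisation gave 1436 higher and 1192 lower, 1424 and 1211, and 1654 and 1402, and a size factor 1303 and 1372, 1298 and 1368, and 1501 and 1550. Without 0 h replicate 2 the counts were 1448, 1938 and 2206. At 24 h the count was 1695 without replicate 1 and 1748 without replicate 2 of that time, at 48 h 2181 and 1933, and at 72 h 2258 without replicate 2. Genes called up with shEVI1 had a median of 0.07 at 24 h (camera p = 2.16e-05, and p = 0.0730 with an estimated correlation) and those called down -0.15 (p = 6.93e-05, and p = 0.0899 with an estimated correlation), against -0.06 for all genes. At 48 and 72 h the set called up had p = 0.00551 and 0.0471, and p = 0.190 and 0.322 with an estimated correlation. The set called down did not pass at these times even at the preset correlation (p = 0.183 and 0.346). No gene was shared between opposite calls of Tet-EVI1 and Tet-shEVI1 at 72 h, as limma called 0 in Tet-EVI1 (795 at an unadjusted p under 0.05). Without Tet-EVI1 72 h replicate 1 both overlaps were smaller than expected of independent lists. Their odds ratios were 0.798 for genes up in Tet-EVI1 and down in Tet-shEVI1 and 0.535 the other way. With a replicate block and without 72 h replicate 2 instead, a setting chosen after seeing the data, the odds ratios were 1.07 and 4.06. Each of these fits rests on 1 library at 72 h, and they differ in direction.

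The single 24 h libraries have no replicate check. Across genes the library labelled Tet-shRen correlated at a mean r of 0.861 with NB508 and 0.802 with 15 T3-2D libraries. The single Tet-shEVI1 library had 0.907 and 0.942 (genes are not independent replicates). Compared with that library, the library labelled Tet-shRen was less like either line. Of 3 genes found in T3-2D but hardly in NB508, Trp53 read 1.13 FPKM in it and 36.0 in Tet-shEVI1, against 36.5 to 56.9 in those 15 and 9.85 in Tet-EVI1 72 h replicate 2, which is not among them; nor are the Tet-shEVI1 time course libraries. Hsd17b7 read 1.17 in it and 5.93 in Tet-shEVI1, but Cdc7 read 8.85, within the T3-2D range of 5.73 to 14.2, and 4.53 in Tet-shEVI1. With that doubt on each direction, Tm4sf4 read 399 in Tet-shEVI1 and 0.923 in the library labelled Tet-shRen, Clca3b 256 and 3.28, the foregut factor Hhex 115 and 2.36, the chemokine Cxcl5 1572 and 51.4, and Lgals2 397 and 12.6. Among the largest values the other way, Ddit3 read 10.9 in Tet-shEVI1 and 1436 in the library labelled Tet-shRen, Gdf15 0.236 and 128, Atf3 3.93 and 338, and Hspa1a 4.57 and 242. Rps27, a ribosomal protein gene, was listed at 0 in Tet-shEVI1 and at 92.4 in the library labelled Tet-shRen. The interferon list had a median difference of -2.96 (percentile 0 of 10000 matched random lists), histones -1.65 (0), ATF4 -0.95 (0), p53 targets -0.72 (0), ribosomal proteins -1.02 (0.02), classical markers 1.19 (99.8), hypoxia 0.81 (99.98), hemidesmosome 0.89 (99.75) and NF-kappaB 0.81 (99.25). Of 10850 genes 3407 were at least 2-fold higher and 957 lower in Tet-shEVI1, and with a size factor 1853 higher and 1997 lower.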

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

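The explanations weighed below were tested after the patterns were seen. Only the test of untreated replicate cultures was written down before its own result. Some first tests were replaced after their results were known. The cell-line tests had used genes 8-fold apart (2 higher in T3-2D, 21 in NB508), of which 82.6% lay nearer NB508 in the library labelled Tet-shRen and 6.15% of the T3-2D level was kept. A test for stress in that library had no bound that could exclude it. A test on r = 0.504, the correlation in the second pattern, could not separate a culture state from an action of EVI1.

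The knockdown effect differed between T3-2D and NB508 in limma's test of the difference for 2465 genes, and 19 of the named genes were among them. As the log2 effect in T3-2D minus that in NB508, the values were -5.66 for Saa3, -2.89 for Aldh1l2, -2.45 for C1s1, -2.29 for Cth, -2.07 for Lcn2, -2.0 for C3, -1.44 for Cdh17 and -0.92 for Ly6c1. Those above 0 were 3.65 for Apoc2, 3.04 for Has2, 2.51 for Klra18, 2.38 for Syt8, 1.67 for Tnnt2, 1.22 for Pcp4l1 and 0.65 for Mecom. Values resting on libraries listed at the floor of a table are not measured folds. They are -4.10 for Ppat, -3.50 for Pigf and -3.60 for Tor1aip1, each listed at 0.1 and 0.1 with shRen in NB508, and -3.61 for Tmem150a, listed at 0 and 0 with shEVI1 in T3-2D. For Pcp4l1, 1 of the T3-2D shEVI1 libraries was listed at 0. The tables of the lines were normalised separately.

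The library labelled Tet-shRen stood apart from the 15 T3-2D libraries it was compared with, which leave out the Tet-shEVI1 time course. Of 68 genes at least 4-fold apart between the lines, 63.2% lay nearer NB508 in it, against 1.47% in the single Tet-shEVI1 library. Another cell line under this label thus stays possible. Across all genes, however, the library labelled Tet-shRen correlated with NB508 at a mean r of 0.861, below the 0.907 of the single Tet-shEVI1 library. An equal mixture with T3-2D cells was argued against by the 5.0% of the T3-2D level kept by the genes higher in T3-2D, a median of only 7 genes, while Cdc7 read 8.85 FPKM against a T3-2D mean of 10.2. Failed estimates were argued against too, since 80.3% of the genes higher in NB508 reached 1 FPKM in it. Stress of T3-2D cells was not excluded, and no second library bears this label.

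The change with stable EVI1 returned in Tet-EVI1 72 h replicate 2 (r = 0.504 across 10323 genes for replicate 2 minus replicate 1, genes not being independent replicates). The level of Mecom was argued against as the cause, since the highest slope of the other 5 induced libraries was 14.4% of its slope. Failed estimates were argued against because r was 0.509 without genes listed at 0. Untreated replicates (replicate 2 minus 1) had r = -0.335 in Tet-EVI1 at 0 h, opposite in sign to this pattern, 0.247 in shRen and -0.00997 in Tet-shEVI1 at 0 h. With a largest absolute r of 0.335, a state unrelated to EVI1 may explain the pattern. The Tet-EVI1 0 h replicates also differed in depth, with 2.89 times as much in replicate 2. Depth and culture state cannot be told apart in that r. Whether EVI1 acts beyond a threshold, a hypothesis only, stays open with 1 such library.

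Gain and loss of EVI1 in T3-2D moved more genes the same way than expected. An offset of the whole scale was argued against, since the lower odds ratio of the same-direction overlaps was 2.16 with a size factor. That variable genes are called more often in either direction was argued against as the only explanation over all calls. It would raise both opposite-direction odds ratios, which were 0.519 and 1.24. A part played by variable genes was not excluded, because an excess of same-direction calls lowers an opposite-direction odds ratio by itself. Among calls of 2-fold or more the explanation by variable genes cannot be told apart, because the lower odds ratio was 2.89 but only 1 of the 2 opposite overlaps passed. Whether other knockdowns share the effect cannot be told apart either, because the genes up in both lay 0.0948 above all genes in Tet-shEVI1 at 24 h and at -0.105 in NB508.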

How the results depend on the processing

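The T3-2D knockdown count was 93 with no filter (30 higher, 63 lower) against 866. Genes up with EVI1 and down with shEVI1 in T3-2D numbered 114 with quantile normalisation and 135 with a size factor. Genes down with EVI1 and up with shEVI1 numbered 4 with no filter and 4 among calls of 2-fold or more, where the direction reversed (exact p = 0.0589). Knockdown calls shared by T3-2D and NB508, up in both, numbered 71 with genes at the floor left out and 5 among calls of at least 2-fold. In the latter, those up in T3-2D and down in NB508 numbered 2 and the converse 2, reversed (exact p = 0.158). With quantile normalisation the T3-2D shEVI1 vs shRen change reversed for Hist1h2ad (0.0292) and Hist1h1c (0.0774), neither past the test. Of the gene lists 0 of 81 calls stayed with an estimated correlation, which can call few lists with 2 or 4 residual degrees of freedom. With stable EVI1 the EGF family had an estimate of -0.101, under the preset 0.01. Its unadjusted camera p still rose from 0.00627 to 0.105. That of basal-like markers (estimate -0.0713) rose from 0.000272 to 0.0633. The failures therefore do not speak against these 2 lists. Estimates well above the preset were found too, with stable EVI1 at 0.610 for hypoxia, 0.688 for cholesterol, 0.284 for NF-kappaB and 0.231 for YAP targets. For such lists the p at the preset correlation can be too small, and the failure cannot be set aside. The causes of the other changes above were not tested.

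For constitutive EVI1 calls in Tet-EVI1 and Tet-shEVI1, the estimated correlation gave camera p (limma) of 0.489 and 0.614 (genes up and down in T3-2D EVI1 vs empty, in Tet-EVI1 24 h vs 0 h), 0.0721 and 0.204 (in Tet-EVI1 72 h vs 0 h), 0.0730 and 0.0899 (genes up and down in T3-2D shEVI1 vs shRen, in Tet-shEVI1 24 h vs 0 h), 0.190 (up, 48 h vs 0 h) and 0.322 (up, 72 h vs 0 h). Without Tet-EVI1 72 h replicate 2 the p were 0.520 and 0.599 at 72 h, and the set down reversed at 48 h (0.943).

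When 1 library is left out, a lone library is assumed to vary like the others. The counts ran from 5918 to 6220 (T3-2D EVI1 vs empty), 80 to 1003 (T3-2D shEVI1 vs shRen), 3125 to 3506 (NB508 shEVI1 vs shRen), 1235 to 2662 (knockdown effect T3-2D minus NB508), 0 to 1 (Tet-EVI1 24 h vs 0 h), 0 to 1 (Tet-EVI1 48 h vs 0 h), 0 to 3201 (Tet-EVI1 72 h vs 0 h), 0 to 1806 (Tet-EVI1 any time vs 0 h), 1448 to 2982 (Tet-shEVI1 24 h vs 0 h), 1933 to 3385 (Tet-shEVI1 48 h vs 0 h), 2206 to 3529 (Tet-shEVI1 72 h vs 0 h) and 1811 to 3237 (Tet-shEVI1 any time vs 0 h). For genes up with EVI1 and down with shEVI1 in T3-2D the range was 14 to 200, down and up 8 to 92, up in both 17 to 180 and down in both 19 to 292. Knockdown calls shared by T3-2D and NB508, up in both, ran from 11 to 89, down in both 21 to 280, up in T3-2D and down in NB508 7 to 100, and down in T3-2D and up in NB508 2 to 73. Genes up at 72 h with Tet-EVI1 and down with Tet-shEVI1 ran from 0 to 158, and the converse 0 to 114. In T3-2D shEVI1 vs shRen, Scel ran from -0.283 to 0.0212, Hist1h2ad from -0.320 to 0.0506 and Hist1h1c from -0.336 to 0.0996, none past the test where reversed.

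Replicate numbers were not taken to pair libraries. With a replicate block the counts were 7096 (T3-2D EVI1 vs empty), 0 in Tet-EVI1 at each time and 2851, 3265 and 3507 in Tet-shEVI1. Replicate differences correlated at 0.107 in the former, 0.525 to 0.662 among 0, 24 and 48 h of Tet-EVI1, -0.237 to 0.0947 with 72 h, and -0.0463 to 0.0136 in Tet-shEVI1. A replicate block without Tet-EVI1 72 h replicate 2, chosen after seeing the data, gave 3, 19 and 154 genes at 24, 48 and 72 h vs 0 h and 9 at any time. The sets opposite in Tet-shEVI1 at 72 h were then 11 and 22. No paired analysis was possible for the T3-2D knockdown because 1 of its columns carries no known number.

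Of the named genes' other values, 190 with a library left out and 95 with no filter no longer passed, as did 13 with quantile normalisation, 4 with a size factor and 4 with the smaller pseudocount. Depth is known only relative to other libraries, so what low depth hides in a table cannot be stated.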

Other observations

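The gain of EVI1 in T3-2D and its loss in NB508, a comparison chosen after seeing the data, held 1043 genes up with EVI1 and down with shEVI1 against 502 expected (Fisher's exact test p = 7.78e-193) and 1406 the other way against 875 (exact p = 2.06e-147). Among calls of 2-fold or more 60 went up and then down against 4.58 expected (exact p = 2.37e-54). The effects correlated at r = -0.364 across genes, which are not independent replicates, against 0.146 for gain and loss within T3-2D. Hypoxia, epithelial and classical PDA genes rose in 28 of 28, 20 of 21 and 15 of 19 with EVI1 and fell in 14 of 28, 13 of 17 and 15 of 19 in NB508, while cell cycle genes fell in 32 of 34 and rose in 28 of 34.

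Overlaps of stable and induced calls were also chosen after seeing the data. With the T3-2D knockdown, Tet-shEVI1 at 72 h shared 61 genes up (20.4 expected, Fisher's exact test p = 2.93e-15) and 161 down (130 expected, exact p = 0.00126). The labels give the hairpin of Tet-shEVI1 for the stable knockdown as well, so its effects apart from EVI1 could be shared. Genes up with stable EVI1 and down at 72 h with Tet-shEVI1 numbered 778 against 738 (exact p = 0.0470, adjusted p = 0.0587). The converse numbered 279 against 299 (exact p = 0.132). Same-direction sets were larger than expected, with 244 up in both against 197 (exact p = 7.39e-05) and 1285 down in both against 1119 (exact p = 1.06e-13). Among calls of 2-fold or more the first set held 17 against 1.05 (exact p = 3.52e-18) and the converse 2 against 0.201 (exact p = 0.0160). There 0 were up in both against 0.324, and 1 was down in both against 0.655.

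In Tet-EVI1 at 72 h, with a replicate block and without 72 h replicate 2 (a setting chosen after seeing the data), limma called 55 genes higher and 99 lower. Mecom rose there (adjusted p = 0.0394). Replication histones were higher in 13 of 22 and NF-kappaB genes lower in 8 of 25. These counts rest on 72 h replicate 1 alone. In the library left out some of these genes lay above the 0 h mean instead: Cxcl2 read 7.36 in replicate 1 and 91.9 in replicate 2 (0 h mean 47.9), Cxcl3 13.7 and 172 (72.8) and Nfkbia 14.1 and 35.4 (23.4). With both libraries limma passed 0 NF-kappaB members at 72 h (795 genes at an unadjusted p under 0.05), with camera adjusted p = 0.821.

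Tet-shEVI1 cells held 104 genes higher and 279 lower at 72 h than at 24 h in limma's test, and Tet-EVI1 cells 0 with 435 at an unadjusted p under 0.05. Of 39 genes at 5 FPKM or more in NB508 libraries and under 1 in 15 T3-2D libraries, 29 reached 1 FPKM in the library labelled Tet-shRen and 1 in the single Tet-shEVI1 library.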
